A study of Mus musculus with 24 samples.

How the data were processed

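The series held RNA sequencing of hind paw punch biopsies, DRG of levels L3 to L5 and the lumbar spinal cord of mice given an LTβR agonist antibody or IgG into the paw. Libraries were made from about 500 ng of RNA with a stranded polyadenylated RNA kit and sequenced as 50 bp single reads. The authors deposited raw read counts per gene, 1 file per library, made with bcl2fastq, TopHat2 on the mm9 build and HTSeq, whose versions, annotation and strand setting were not given in the sources used here. Each file held 22609 gene symbols and 5 summary lines, which were removed from the counts. No normalization had been applied, and there were 0 columns of other samples. HTSeq leaves out reads placed at several positions, so genes with near-identical copies read low; Gapdh had 27 to 77 counts per library.

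The 24 libraries formed 8 groups of 3 by the labels. The labels number the samples but do not say that each is a separate animal, so p-values measure the spread between these samples. Of 24 pairs of replicates, 0 were identical. Reads counted in genes numbered 15.7 to 41.0 per library in units of 1e6, and 16987 to 17643 genes were detected.

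Genes were tested within each tissue with the edgeR quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM normalization, the default filter on low counts and robust dispersions. This kept 15287 genes in paw, 15461 in DRG and 15096 in spinal cord. Adjusted p are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05, and tests were 2-sided. CPM are normalised for library size and TMM factor, errors of CPM are SD and errors of log2 fold changes are SE. The difference between paw and DRG was the interaction term of a fit to 18 libraries. Scores of a list are the mean over its genes of log2 CPM, with a prior count of 2, centred within the tissue.

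Before the data were examined, 58 gene lists with 891 symbols, the comparisons, most alternatives and a rule for naming genes were fixed. Of the symbols, 861 matched as written, 18 by an older symbol and 12 had no match; 37 lists in paw, 41 in DRG and 42 in spinal cord had at least 5 tested genes. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated per list, and with fry. The rule named, among genes past the threshold with a mean log2 CPM of at least 0 and groups that did not overlap, the 12 with the largest change in each direction, leaving out provisional gene models. It added the 4 members with the smallest p of each list called by camera or with 3 members past the threshold, a set of LTβR pathway genes whatever their p, and the 5 genes with the smallest p where fewer than 5 passed. For the difference between tissues it named the 10 genes with the smallest p past the threshold, or the 5 with the smallest p where none passed. Not every gene the rule allowed is given.

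The pipeline was tested on simulated data with the library sizes, gene means and dispersions of these libraries. Each gene was drawn on its own, so structure shared between genes, such as muscle content, was absent. Only genes with a mean of at least 1 CPM were changed. Recovery and false calls in the real data may therefore be worse. edgeR recovered 50 to 88 of 100 genes changed 2-fold within a tissue and 85 to 98 of 100 changed 4-fold, with 4 to 16 false calls among 141 to 195. Alternatives were RLE and upper-quartile normalization, no filter and a stricter filter of 1 CPM in 3 libraries, limma voom with quality weights, DESeq2 1.42.0, the replicate number as a block, fits of only the groups compared, and each library left out in turn. Covariates for skeletal muscle in paw and DRG and for meningeal genes in spinal cord, and a block of paw and DRG libraries of the same group and number, were added after seeing the data. The lists shared by both days were set against 50 simulations, also with each gene drawn on its own, in which no gene differed between groups.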

Results

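Gene expression was measured by RNA sequencing of polyadenylated RNA in 24 libraries from hind paw skin, dorsal root ganglia (DRG) and lumbar spinal cord of male C57 mice aged 8 to 12 weeks. The DRG hold the cell bodies of the sensory neurons that innervate the paw. Mice had received an antibody that activates the lymphotoxin beta receptor (LTβR), a receptor of the tumour necrosis factor family that signals through the non-canonical NF-κB pathway, or control IgG, by injection of 10 µg into the hind paw. Agonist tissue was taken 1 day after 1 injection, or on day 6 after 2 injections, and control tissue was taken 1 day after IgG. Paw and DRG each had a control, a day-1 and a day-6 group, and spinal cord had a day-1 and a day-6 group, with 3 libraries per group. Day 6 therefore differed from the other groups in both time and number of injections. The labels differ on its timing, since the sample titles count the days from the first injection and the series design counts them after both, so day 6 is the name of the group and its exact interval is uncertain. In units of 1e6, the reads counted in genes ranged from 24.2 to 41.0 per library in paw, from 21.6 to 34.2 in DRG and from 15.7 to 26.3 in spinal cord.

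Several features of the libraries stood apart from the treatment groups. Paw control 1 held little skeletal muscle RNA, with Acta1, the skeletal muscle actin, chosen after its values were seen, at 31.1 CPM against 778 to 8054 CPM in the other 8 paw libraries. In DRG the skeletal muscle genes had scores of 2.72, 3.13 and 2.99 in control 2, control 3 and day-1 library 1, and of -2.78, -2.58 and -2.74 in control 1, day-1 library 3 and day-6 library 2, as mean centred log2 CPM. In spinal cord the meningeal genes scored 0.55, 0.72 and 0.64 in day-1 library 2, day-6 library 1 and day-6 library 3, and -0.93, -0.43 and -0.55 in the other libraries. In DRG control 1, HTSeq assigned 31.5% of the uniquely placed reads to no annotated feature, against 13.1 to 13.8% in the other 8 DRG libraries. It also had more alignments that were not unique, 29.8 in units of 1e6 against 15.4 to 20.1 in those 8.

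**Figure D1:**
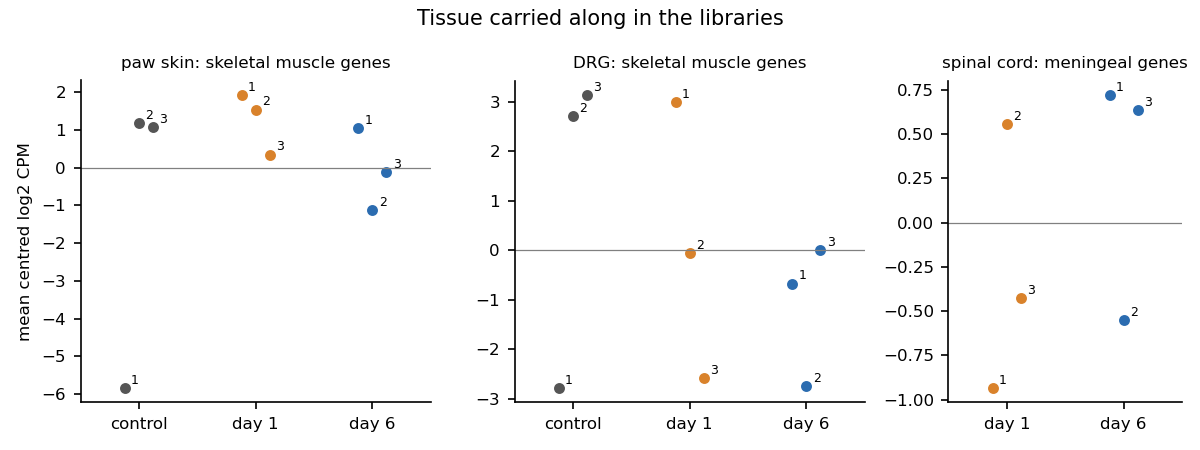
Mean centred log2 CPM of the skeletal muscle genes in paw and DRG libraries and of the meningeal genes in spinal cord libraries, with 1 point per library, its replicate number beside it, and the groups along the horizontal axis. Paw control 1 lies far below the other paw libraries, and DRG and spinal cord libraries of the same group spread widely.

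The first comparison asked how paw skin responded 1 day after the agonist. Relb, the NF-κB subunit activated downstream of LTβR, rose 2.66-fold, from 14.5 ± 1.26 to 38.5 ± 2.40 CPM (SD, n = 3 per group), a log2 fold change of 1.41 ± 0.12 (SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0157). It was the only gene of 15287 past the threshold, with 1626 at an unadjusted p under 0.05. The 4 genes with the next smallest p did not pass: Nfkb2, which encodes the p100 precursor of the same pathway, at a log2 fold change of 1.22 ± 0.15, Nfkbie, an inhibitor of NF-κB, at 1.68 ± 0.23, Bcl6b at 1.46 ± 0.19 and the tumour suppressor gene Dlc1 at 0.71 ± 0.09, all with an edgeR adjusted p of 0.140. Ltbr itself was at 52.3 ± 5.01 CPM against 48.1 ± 7.89 CPM in controls, and its ligand genes Lta, Ltb and Tnfsf14 averaged under 1 CPM in every paw group. The pathway genes Ccl19 and Ccl21a had 0 counts in every paw library and Madcam1 at most 2, so they could not be tested in paw.

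Among the gene lists fixed before the data were examined, 14 of 37 were higher and 7 lower on day 1 in paw by camera with its preset correlation. With an estimated correlation 0 of the 21 calls were left, with a smallest adjusted p of 0.505. The list of LTβR signalling and NF-κB genes was higher (20 genes, camera adjusted p = 1.08e-06), with 1 member past the threshold over all genes and 8 higher when adjusted over the list alone. The interferon-gamma targets were higher as a set, with a median log2 fold change of 1.31 over 17 genes, none past the threshold over all genes and 12 higher adjusted over the list alone; the GTPase gene Gbp2 was at 1.76 ± 0.48 and the transcription factor Irf1 at 1.31 ± 0.24. Day-1 library 2 stood apart for Gbp2, at 57.8 CPM against 21.7 and 17.3 CPM in day-1 libraries 1 and 3. The list call was kept whichever library was left out. The genes of MHC class I presentation were higher as well, with 0 of 14 past the threshold and 9 adjusted over the list alone, among them the peptide transporter Tap2 at 0.81 ± 0.18 and the immunoproteasome subunit Psmb8 at 1.04 ± 0.26. These 3 lists had adjusted p = 0.505, 0.543 and 0.543 with an estimated correlation, and fry called the LTβR list alone (adjusted p = 0.0171).

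Cell cycle genes were lower as a set in paw on day 1. All 26 had negative log2 fold changes, with a median of -0.83, 0 past the threshold over all genes and 25 lower adjusted over the list alone; the mitotic genes Cenpf and Cdc20 were at -1.39 ± 0.28 and -1.10 ± 0.25. Stress keratinocyte genes, induced in injured or inflamed epidermis, were lower with a median of -1.46 over 25 genes and 0 past the threshold or adjusted over the list alone, and Il1f9, an epidermal cytokine, was at -1.15 ± 0.31. The stress keratinocyte scores of controls 1 and 2, at 1.47 and 1.64, stood apart from control 3, at -0.07, which lay among the day-1 libraries at 0.12, -0.72 and -0.16, so 2 control libraries carried much of this fall. Basal keratinocyte genes were lower with 0 of 11 past the threshold and 5 adjusted over the list alone; Krt14, the basal layer keratin, was at -0.88 ± 0.23. These 3 calls were lost with an estimated correlation (adjusted p = 0.543, 0.563 and 0.543 with an estimated correlation). Vcam1 and Sele, adhesion molecules of activated endothelium, were at 2.23 ± 0.41 and 1.47 ± 0.21, and the monocyte chemokine Ccl2 was at 2.47 ± 0.48, with edgeR adjusted p of 0.326, 0.177 and 0.348. Mast cell, mural and Schwann lists were higher too (camera adjusted p = 0.0108, 0.0423 and 0.0108). They were kept in 5, 3 and 3 of 6 fits with a library left out. Neutrophil, hair follicle and differentiated keratinocyte lists were lower (0.0172, 0.0271 and 0.0327), kept in 2, 3 and 2.

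The Relb call on day 1 held without paw control 1 and was lost when any of the other 5 libraries was left out, with an adjusted p of up to 0.0973 and log2 fold changes between 1.36 and 1.47. It was also lost when the day-6 libraries were left out of the fit, and with the replicate number as a block. DESeq2 called 209 genes in this comparison, and leaving out paw control 1 reduced the lists called from 21 to 13. Skeletal muscle genes were higher on day 1 (adjusted p = 0.699 with an estimated correlation), and without paw control 1 this call was lost (camera adjusted p = 0.784).

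**Figure D2:**
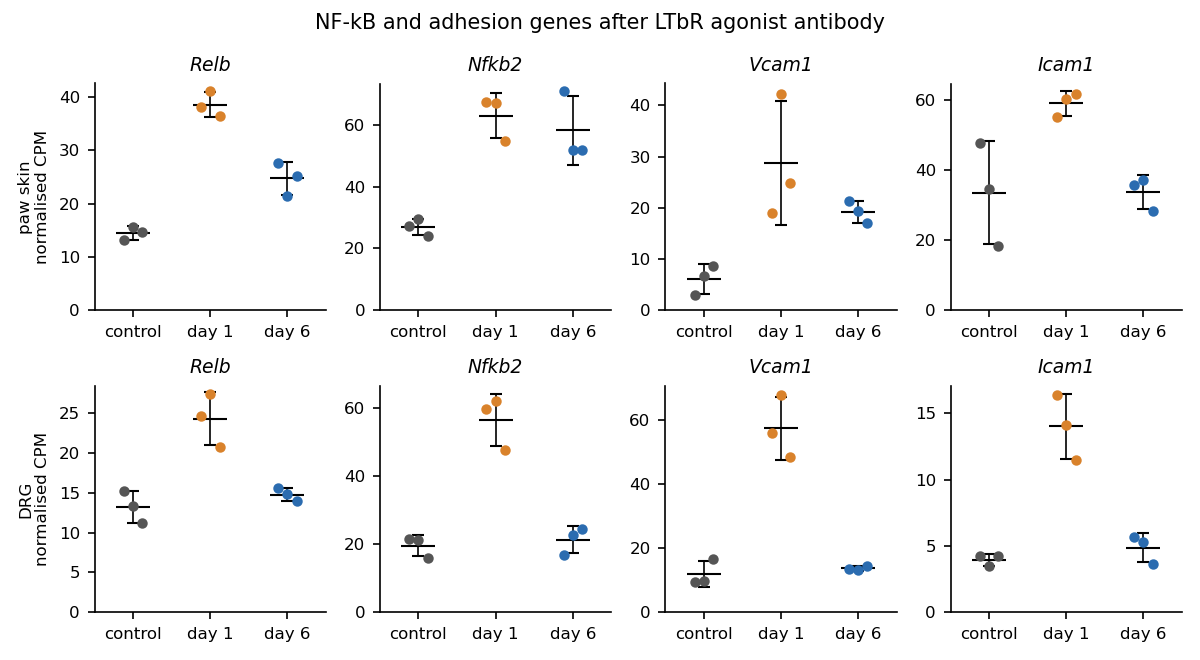
Normalised CPM of Relb, Nfkb2, Vcam1 and Icam1 in paw skin (top) and DRG (bottom) of control, day-1 and day-6 groups, with 1 point per library and bars for the mean and SD of 3 libraries. In DRG the day-1 libraries lie above both other groups for each gene, and in paw the Relb means were 38.5 CPM on day 1 and 24.7 CPM on day 6 against 14.5 CPM in controls.

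The day-6 comparison with controls asked what the paw held after 2 injections. Of 15287 genes, 102 rose and 6 fell, with 1489 at an unadjusted p under 0.05. Ccr2, the receptor that brings monocytes into tissue, rose 5.58-fold to 80.0 ± 17.0 CPM from 14.3 ± 4.81 CPM (SD, n = 3 per group), and Mpeg1, a pore-forming protein of macrophages, rose 5.34-fold to 63.8 ± 7.82 CPM. Cd33, a sialic acid receptor of myeloid cells, had a log2 fold change of 2.14 ± 0.25, Emr1, which encodes the macrophage marker F4/80, of 1.98 ± 0.25, and Csf1r, the receptor for the macrophage growth factor, of 1.34 ± 0.16, with edgeR adjusted p of 0.0147, 0.0164 and 0.0147. Of 21 macrophage and monocyte markers, 7 rose and 16 were higher adjusted over the list alone, with a median log2 fold change of 1.34.

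MHC class II presentation rose as a list in paw on day 6, with 7 of its 8 measured genes past the threshold and all 8 adjusted over the list alone. The invariant chain Cd74 rose to 292 ± 26.6 CPM from 147 ± 11.9 CPM, H2-Eb1 had a log2 fold change of 0.84 ± 0.09 and the peptide loading gene H2-DMb1 of 1.26 ± 0.13 (edgeR adjusted p = 0.0147 for each). This call held with an estimated correlation (adjusted p = 0.00762 with an estimated correlation), as did that of the dendritic and Langerhans cell markers (0.0318), of which 0 of 13 passed over all genes and 5 adjusted over the list alone. Complement genes were higher, with 4 of 15 past the threshold and 9 adjusted over the list alone: C3, the central complement component, rose 5.22-fold, and C1qa and C1qc, subunits of the first component, had log2 fold changes of 1.28 ± 0.20 and 1.25 ± 0.22. The macrophage and complement calls were lost with an estimated correlation (adjusted p = 0.246 and 0.291 with an estimated correlation).

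Other cell-type lists moved in paw on day 6 too, with 0 members past the threshold. T cell markers were higher with a median of 0.90 and 3 of 8 adjusted over the list alone, and basal keratinocyte genes were lower with a median of -0.41 and 0 of 11 (adjusted p = 0.207 and 0.291 with an estimated correlation), and both calls were kept whichever library was left out. Mast cell markers were higher with a median of 0.57 and fibroblast and collagen genes with 0.21, with 0 of 12 and 0 of 20 adjusted over the list alone (adjusted p = 0.615 and 0.749 with an estimated correlation). These 2 calls were kept in 4 and 2 of the 6 fits with a library left out.

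Of the 20 tested genes of LTβR signalling, 3 passed in paw on day 6. Nfkb2 had a log2 fold change of 1.11 ± 0.15, Nfkbie of 1.67 ± 0.23 and Relb of 0.77 ± 0.12 (edgeR adjusted p = 0.0209, 0.0209 and 0.0314). Adjusted over the list alone 5 passed, 15 members were positive and 5 negative, and the list call was lost with an estimated correlation (adjusted p = 0.246 with an estimated correlation). Vcam1 was at 19.3 ± 2.16 CPM against 6.14 ± 2.85 CPM, which did not pass (adjusted p = 0.144), and Icam1 was at 33.8 ± 4.81 against 33.7 ± 14.6 CPM. Among the 6 genes that fell were Saa3, an acute-phase protein, at -4.19 ± 0.50, the metalloproteinases Adamts1 and Adamts9, both at -1.12, with SE of 0.17 and 0.19, and the mitochondrial superoxide dismutase Sod2 at -0.39 ± 0.07. Stress keratinocyte genes were lower as a set with a median of -1.37 and 0 of 25 past the threshold or adjusted over the list alone (adjusted p = 0.333 with an estimated correlation), again against high scores in controls 1 and 2 alone, with the day-6 libraries at -1.45, 0.54 and -1.37.

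**Figure D3:**
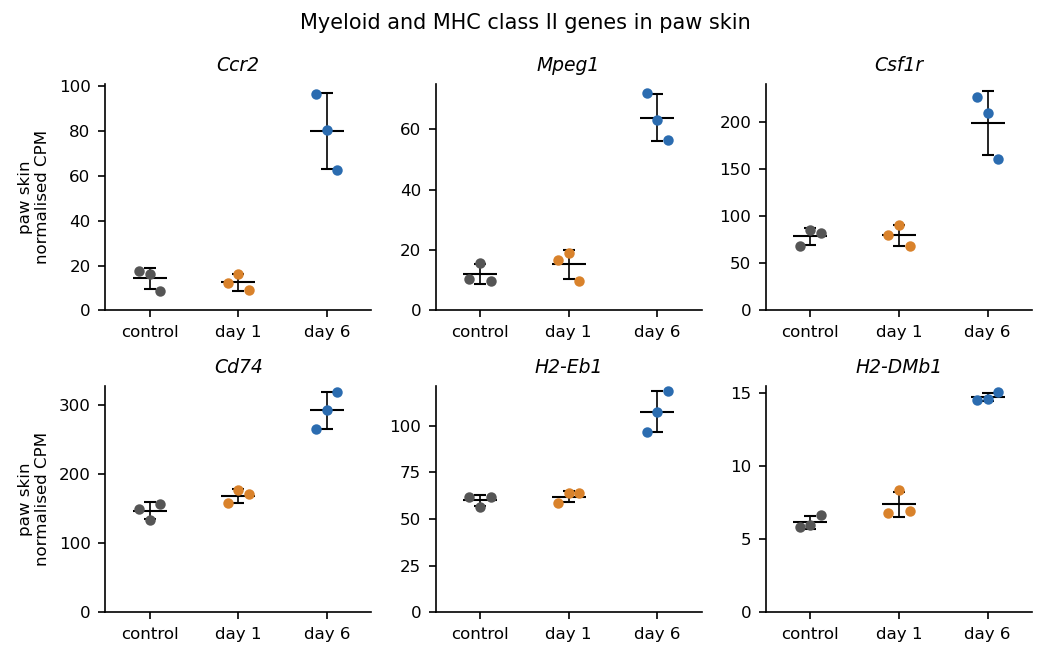
Normalised CPM of Ccr2, Mpeg1, Csf1r, Cd74, H2-Eb1 and H2-DMb1 in the 9 paw libraries by group, with 1 point per library and bars for the mean and SD of 3 libraries. The day-6 libraries lie above every control and day-1 library for each gene.

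With single libraries left out, the day-6 log2 fold changes in paw ran from 2.23 to 2.70 for Ccr2, 0.92 to 1.06 for Cd74 and 2.28 to 2.67 for Mpeg1. The number of genes called on day 6 in paw was less stable. It was 47 without control 1 and 0 without control 2, control 3, day-6 library 1 or day-6 library 2, and was also 0 when the day-1 libraries were left out of the fit; Cd74, H2-DMb1 and Mpeg1 then had adjusted p of up to 0.0709, 0.0709 and 0.0759 across the left-out libraries, and Relb, Adamts9 and Sod2 were lost whichever of the 6 was left out, with adjusted p of up to 0.141, 0.202 and 0.223. With the muscle score of each library as a covariate, an alternative chosen after seeing the data, 211 genes were called, 108 of them shared with the calls above, and DESeq2 called 509.

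Between day 1 and day 6 in paw, 145 genes rose and 12 fell, with 2137 at an unadjusted p under 0.05. Ccr2 rose 6.39-fold from 12.5 ± 3.63 CPM on day 1 to 80.0 ± 17.0 CPM on day 6 (SD, n = 3 per group), and 8 of 21 macrophage and monocyte markers passed the threshold, 16 adjusted over the list alone, with Csf1r at a log2 fold change of 1.32 ± 0.16 and the IgG receptor Fcgr3 at 1.58 ± 0.19 (edgeR adjusted p = 0.0202 for both). Tlr9 and Tlr8, endosomal receptors for nucleic acids, rose by 2.04 ± 0.26 and 2.09 ± 0.37. Of the MHC class II genes 6 of 8 rose, and all 8 were higher adjusted over the list alone. The MHC class II call held with an estimated correlation (adjusted p = 0.0198 with an estimated correlation) and the macrophage call did not (0.351). Cd4, carried by helper T cells and some myeloid cells, rose 3.88-fold to 2.13 ± 0.644 CPM.

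Other lists were lower in paw on day 6 than on day 1, with 0 members past the threshold or adjusted over the list alone. Skeletal muscle genes had a median log2 fold change of -1.17, mural and smooth muscle markers of -0.37 and Schwann cell genes of -0.40 (adjusted p = 0.914 for each with an estimated correlation). All 33 oxidative phosphorylation genes were negative, with a median of -0.34 (adjusted p = 0.697 with an estimated correlation). With single libraries left out, only the oxidative phosphorylation call of these 4 was kept in all 6 fits.

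Cell cycle genes were higher in paw on day 6 than on day 1. All 26 had positive log2 fold changes with a median of 1.05, 8 passed the threshold and 22 were higher adjusted over the list alone. Cyclin genes Ccna2 and Ccnb2 rose 2.21-fold and 2.23-fold, and Kif20a, a kinesin of cytokinesis, had a log2 fold change of 1.32 ± 0.19 (edgeR adjusted p = 0.0202, 0.0202 and 0.0249). The list call was lost with an estimated correlation (adjusted p = 0.351 with an estimated correlation). Relb fell by 0.64 on the log2 scale, Sele from 52.3 ± 15.6 to 22.2 ± 2.36 CPM and Bcl6b from 15.1 ± 0.543 to 7.70 ± 1.18 CPM, with edgeR adjusted p of 0.0459, 0.0389 and 0.0495, while Nfkb2 was at -0.11 ± 0.15. The calls of Relb, Sele and Bcl6b were lost whichever of the 6 libraries was left out, with adjusted p of up to 0.192 for Relb, 0.203 for Sele and 0.229 for Bcl6b. The count of 157 genes became 42 without day-1 library 2, and 0 without day-1 library 1, day-1 library 3, day-6 library 1 or day-6 library 2. It was 367 with the muscle covariate, chosen after seeing the data, 623 with limma voom and 737 with DESeq2.

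The calls shared by day 1 and day 6 against the paw controls amounted to 1 gene, Relb. Both comparisons used the same 3 controls, and 50 simulations of unchanged groups gave a mean of 0.02 shared higher genes, with a range of 0 to 1; independent lists of these sizes would share 0.00667. Across the 15287 genes, the log2 fold changes of both days had a correlation of 0.361 against 0.508 in the simulations, and a covariance of 0.0655 against 0.0672, with a simulated range of 0.0614 to 0.0764. The 3 controls cannot be divided into parts of 2, so part of any shared signal may come from the controls themselves. No library could be left out without losing the shared call.

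In the DRG, the day-1 comparison asked whether the ganglia responded to an injection in the paw. Of 15461 genes, 25 rose and 1 fell, with 1144 at an unadjusted p under 0.05. Cx3cl1, the chemokine fractalkine, rose 2.95-fold from 11.6 ± 1.18 to 34.3 ± 0.878 CPM (SD, n = 3 per group, edgeR adjusted p = 8.35e-05). Vcam1 rose 4.79-fold to 57.5 ± 9.78 CPM, Icam1, another adhesion molecule, 3.53-fold to 14.0 ± 2.44 CPM, and Nfkb2 2.89-fold to 56.4 ± 7.64 CPM (edgeR adjusted p = 0.0124, 0.00373 and 0.0139). Relb and Nfkbie had log2 fold changes of 0.88 ± 0.12 and 0.89 ± 0.09, with edgeR adjusted p of 0.0228 and 0.00373. Ltbr was at 38.1 ± 2.43 CPM against 34.1 ± 1.67 CPM and did not pass (adjusted p = 0.672).

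Csf1, the macrophage growth factor, rose 1.74-fold in DRG on day 1 and Ptges, a synthase of prostaglandin E2, 1.92-fold (edgeR adjusted p = 0.00396 and 0.00373). The cytokine receptor subunits Csf2rb2 and Il2rg had log2 fold changes of 1.59 ± 0.18 and 1.58 ± 0.25, and the homeobox gene Meox1 of 1.22 ± 0.16. Arntl, the clock gene also called Bmal1, rose 2.11-fold from 7.43 ± 0.0527 to 15.7 ± 2.58 CPM. Mrc1, the macrophage mannose receptor, had a log2 fold change of 0.59 ± 0.09 and the transporter gene Slco1a5 of 1.05 ± 0.17 (edgeR adjusted p = 0.0454 and 0.0484).

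**Figure D4:**
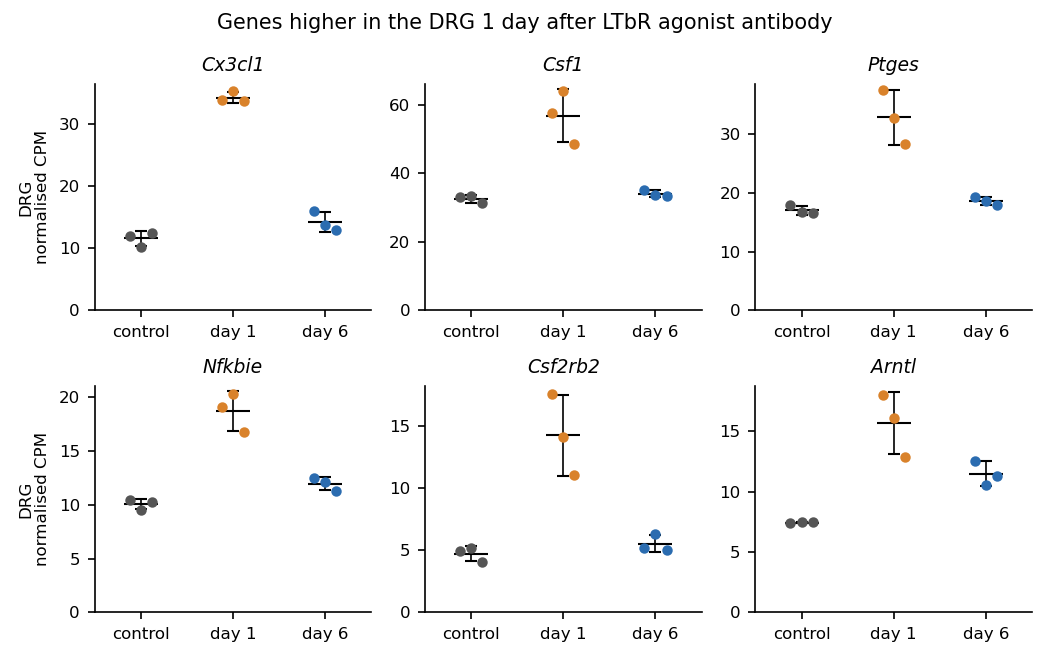
Normalised CPM of Cx3cl1, Csf1, Ptges, Nfkbie, Csf2rb2 and Arntl in the 9 DRG libraries by group, with 1 point per library and bars for the mean and SD of 3 libraries. The day-1 libraries lie above every control library for each gene.

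Of 41 lists tested in DRG, 18 were higher and 6 lower on day 1 by camera with its preset correlation. With an estimated correlation 0 of the 24 calls were left, with a smallest adjusted p of 0.0891. All 18 tested genes of LTβR signalling and NF-κB had positive log2 fold changes, with 3 past the threshold and 8 adjusted over the list alone. Of the 9 tested lymphoid-organising targets of LTβR, 4 rose, with 6 higher and 1 lower adjusted over the list alone and a median of 1.53. The pathway genes Ccl19 and Ccl21a had 0 counts in every DRG library, and Cxcl13 and Madcam1 had at most 7 and 6. None of these genes could be tested in DRG, so nothing is known here of their response. Complement genes were higher with a median of 0.40, 0 of 15 past the threshold and 11 adjusted over the list alone, and chemokines were higher with 1 of 18 past the threshold and 7 adjusted over the list alone. These 4 calls had adjusted p = 0.0891, 0.139, 0.0891 and 0.139 with an estimated correlation, and fry called each of them (adjusted p = 0.00534, 0.00534, 0.0119 and 0.0219). The chemokine genes Ccl2 and Cxcl10 were at 2.55 ± 0.43 and 2.85 ± 0.72 without passing the threshold.

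Type I interferon-stimulated genes were higher in DRG on day 1 as a set, with all 25 positive, a median of 0.62 and 0 past the threshold or adjusted over the list alone. Day-1 library 2 stood apart for the interferon-induced gene Rsad2, at 51.1 CPM against 21.5 and 20.3 CPM in day-1 libraries 1 and 3. The list call was kept whichever library was left out. Neutrophil markers were lower, with all 15 negative, a median of -1.20 and 0 past the threshold or adjusted over the list alone; Ngp, a neutrophil granule protein, was at 18.2 ± 6.53 against 47.4 ± 22.4 CPM. Both calls were lost with an estimated correlation (adjusted p = 0.440 and 0.427 with an estimated correlation). Skeletal muscle genes were lower on day 1 with a median of -0.56 and 0 of 22 past the threshold or adjusted over the list alone (adjusted p = 0.721 with an estimated correlation), beside all the groups named above. The muscle call was kept in 2 of the 6 fits with a library left out. Without day-1 library 3 its direction turned to higher (camera adjusted p = 0.695).

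Other cell-type lists moved in DRG on day 1 as well. Macrophage and monocyte markers were higher with a median of 0.25, 15 of 20 positive, 1 past the threshold, and 3 higher and 1 lower adjusted over the list alone. Microglia genes were higher with a median of 0.19, 0 of 17 past the threshold and 5 adjusted over the list alone. Both calls were kept whichever library was left out, and lost with an estimated correlation (adjusted p = 0.440 and 0.328 with an estimated correlation). Fibroblast and collagen genes were higher with a median of 0.26, 18 of 20 positive, 0 past the threshold and 2 adjusted over the list alone (adjusted p = 0.427 with an estimated correlation), a call kept whichever library was left out. Meningeal genes and mural markers were higher, each with a median of 0.16 (adjusted p = 0.487 for both with an estimated correlation), and pan-neuronal genes were lower with a median of -0.05 (0.606). In these 3 lists 0 members passed the threshold or adjusted over the list alone, and each call was lost without control 1 (adjusted p = 0.471, 0.146 and 0.253).

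The DRG calls on day 1 numbered 12, 8 and 14 without control 1, 2 and 3, and 12 and 10 without day-1 libraries 1 and 2. Cx3cl1, Icam1, Nfkbie, Csf1, Ptges, Csf2rb2 and Arntl stayed past the threshold whichever library was left out, with adjusted p of at most 0.0371. Vcam1 was lost without control 2 or day-1 library 1 (adjusted p up to 0.0786), Nfkb2 without control 1, control 2 or day-1 library 1 or 2 (up to 0.110), and Relb without control 2, control 3 or day-1 library 1 or 2 (up to 0.130). Il2rg and Meox1 were lost without 4 of the 6 libraries each, and Mrc1 and Slco1a5 whichever was left out. With DESeq2 131 genes were called, and with the DRG day-6 libraries left out of the fit, 11.

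By day 6 the DRG did not differ from controls at any of 15461 genes by edgeR, with 557 at an unadjusted p under 0.05 and a smallest adjusted p of 0.995; limma voom also called 0 and DESeq2 called 2. Nfkb2 was at 21.3 ± 3.97 CPM against 19.6 ± 3.06 CPM in controls, Vcam1 at 13.7 ± 0.692 against 11.9 ± 3.99 CPM and Icam1 at 4.86 ± 1.09 against 3.97 ± 0.441 CPM (SD, n = 3 per group). The 5 genes with the smallest p, none past the threshold, included Megf11 at 0.73 ± 0.13, the mitotic gene Cenpf at 1.35 ± 0.25 and Arntl at 0.63 ± 0.12. In simulated data of this comparison edgeR recovered 88 of 100 genes changed 2-fold. Those data lacked structure shared between genes and held many changed genes, so power in the real data may be lower.

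Among the lists, nerve injury genes, induced in sensory neurons after axonal damage, were higher in DRG on day 6. Of 21, 19 were positive with a median of 0.17, and 0 passed over all genes or adjusted over the list alone. Sprr1a was at 2.43 ± 0.0894 CPM against 0.899 ± 0.486 CPM and Stmn4 at 16.1 ± 1.74 against 12.6 ± 0.626 CPM. The call was lost with an estimated correlation (adjusted p = 0.448 with an estimated correlation). Skeletal muscle genes were lower with a median of -3.42 and 0 of 22 past the threshold or adjusted over the list alone (adjusted p = 0.958 with an estimated correlation), a call lost without control 3 (0.0717), with Casq1 at 16.7 ± 6.92 against 92.1 ± 72.5 CPM. In the comparison of both days with the 3 DRG controls 0 genes were shared, against a simulated mean of 0.02. Across genes the correlation was 0.478 against 0.504 in the simulations, and the covariance 0.05104 against 0.0394, just above the highest of the 50 simulated values, which ran from 0.0336 to 0.05097.

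Between day 1 and day 6 in DRG, 14 genes fell and 2 rose, with 1056 at an unadjusted p under 0.05. Cx3cl1 fell from 34.3 ± 0.878 to 14.2 ± 1.60 CPM, Vcam1 from 57.5 ± 9.78 to 13.7 ± 0.692 CPM and Icam1 from 14.0 ± 2.44 to 4.86 ± 1.09 CPM (SD, n = 3 per group, edgeR adjusted p = 6.17e-04, 0.0196 and 0.0107). Nfkb2, Csf1, Ptges and Csf2rb2 fell by 1.41, 0.74, 0.82 and 1.37 on the log2 scale. Tnfaip3, an inhibitor of NF-κB, fell by 1.05 and the complement gene C1qa by 0.54, while Relb, at -0.72 ± 0.12, did not pass (edgeR adjusted p = 0.0375, 0.0452 and 0.0795). Cenpf rose 4.03-fold and Folh1, a glutamate carboxypeptidase, 1.48-fold.

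Lists followed the same genes between the days. LTβR signalling genes were lower with 3 of 18 past the threshold and 9 adjusted over the list alone, complement genes with 1 of 15 and 10, and chemokines with 1 of 18 and 6 (adjusted p = 0.0985 for each with an estimated correlation). Neutrophil markers were higher with a median of 1.27 and 0 of 15 past the threshold or adjusted over the list alone (adjusted p = 0.405 with an estimated correlation). Fibroblast and collagen genes were lower whichever library was left out (camera adjusted p at most 2.61e-06). Schwann, mural and microglia lists were lower (camera adjusted p = 0.00298, 0.0435 and 0.0422), kept in 4, 4 and 2 of 6 such fits. Pan-neuronal and satellite glia genes were higher (5.34e-04 and 0.0468), kept in 5 and 3. All these calls were lost with an estimated correlation. Cx3cl1 stayed past the threshold whichever library was left out, while Icam1 was lost without day-1 library 1 or day-6 library 2 or 3 (adjusted p up to 0.0663). C1qa was lost whichever library was left out (up to 0.210), Tnfaip3 without 5 of the 6 (up to 0.207), Vcam1, Nfkb2 and Csf2rb2 without 4 (up to 0.184, 0.138 and 0.116), and Csf1 and Ptges without 3 (up to 0.0911 for both). Cenpf was lost without 5 (up to 0.111) and Folh1 without 3 (up to 0.0877). The count of 16 became 1 without day-1 library 1 and 8, 2 and 2 without day-6 libraries 1, 2 and 3, and was 27 with no filter on low counts and 106 with DESeq2.

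Whether paw and DRG responded differently was tested as an interaction over 16461 genes and 18 libraries. At day 1 edgeR found 0 genes with a different response, with 1594 at an unadjusted p under 0.05 and a smallest adjusted p of 0.194, while limma voom called 0 and DESeq2 59. The count was 1 without paw control 1 or paw control 3. Among the 5 genes with the smallest p were Dbc1, at 2.51 in paw and -0.04 in DRG, Amph, at 1.03 in paw and -0.04 in DRG, Cx3cl1, at 1.56 ± 0.13 in DRG and 0.46 ± 0.13 in paw, and Ptges, at 0.94 ± 0.20 in DRG and -0.67 ± 0.20 in paw. At day 6, 82 genes differed, 79 with a larger log2 fold change in paw and 3 with a larger one in DRG.

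The 10 genes with the smallest p at day 6 all had the larger value in paw. Mpeg1 was at 2.42 ± 0.22 in paw and 0.30 ± 0.21 in DRG, Cd74 at 0.99 ± 0.10 and -0.07 ± 0.10, and H2-DMb1 at 1.26 ± 0.12 and 0.05 ± 0.11 (edgeR adjusted p of the difference = 0.00750, 0.00526 and 0.00526). The lectin Mgl2, carried by dermal macrophages and dendritic cells, was at 1.47 ± 0.19 and -0.44 ± 0.18, and Lcp1, a leukocyte actin-bundling protein, at 1.30 ± 0.13 and -0.04 ± 0.13. The 9 genes in the plot of both tissues stayed past the threshold whichever of the 12 libraries was left out. The total was 41, 40 and 20 without DRG control 1, 2 and 3, 39, 19 and 28 without DRG day-6 libraries 1, 2 and 3, 28, 28 and 173 without paw day-6 libraries 1, 2 and 3, and 234 with DESeq2. With paw and DRG libraries of the same group and number as a block, chosen after seeing the data, 34 genes were called, 31 of them among the 82.

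**Figure D5:**
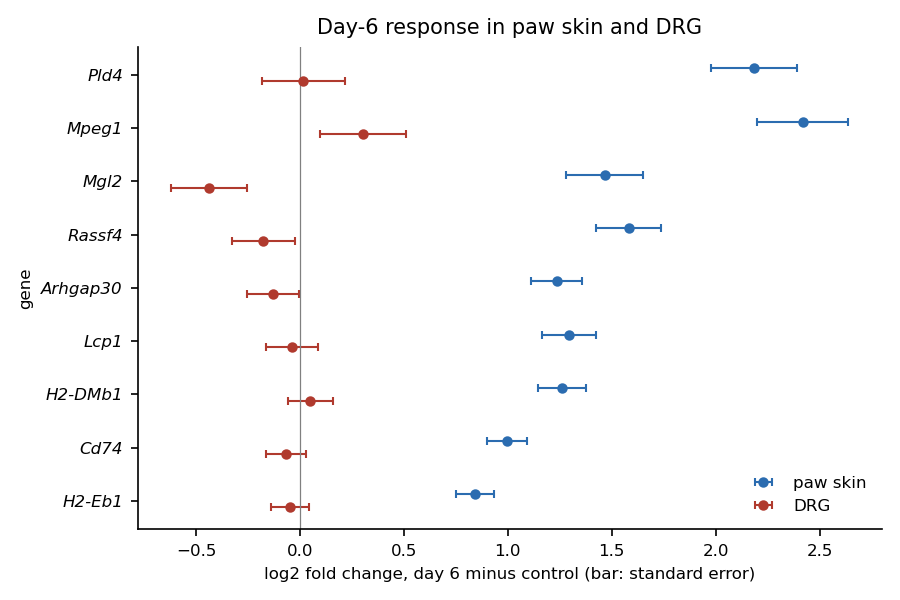
Log2 fold change of day 6 against control, with its standard error, in paw skin (blue) and DRG (red) for 9 of the 10 genes with the smallest p of the difference between tissues. Paw values run from 0.84 to 2.42 and DRG values from -0.44 to 0.30.

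In the spinal cord only the agonist groups were analysed here, so the comparison was of day 6 with day 1. No gene of 15096 passed by edgeR, with 1464 at an unadjusted p under 0.05 and a smallest adjusted p of 0.463; limma voom called 0 and DESeq2 64. Fabp7, a fatty acid binding protein of astrocytes and radial glia, was at 48.2 ± 2.43 CPM on day 6 against 33.3 ± 2.21 CPM on day 1, and Tek, an endothelial receptor, at 21.6 ± 1.13 against 14.5 ± 0.786 CPM (SD, n = 3 per group). Neutrophil markers were higher as a list, with all 12 positive, a median of 3.32, 0 past the threshold over all genes and 9 adjusted over the list alone (adjusted p = 0.685 with an estimated correlation). Erythroid markers moved with them, at a score of 2.29 in day-6 library 1 and between -1.49 and 0.38 in the other 5 libraries. Mpo, the neutrophil peroxidase, was at 9.33, 1.56 and 2.97 CPM in the day-6 libraries and between 0.420 and 0.735 CPM in the day-1 libraries.

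Cell cycle genes were higher in spinal cord on day 6, with all 22 positive and 0 past the threshold or adjusted over the list alone, and Mki67 was at 5.04 ± 4.19 CPM against 0.616 ± 0.274 CPM. Its values in day-6 libraries 1, 2 and 3 were 9.79, 1.85 and 3.47 CPM. The erythroid gene Slc4a1, at 30.8, 3.21 and 6.25 CPM, and Mpo were also highest in day-6 library 1. The cell cycle call was kept whichever library was left out (camera adjusted p at most 2.76e-05). Whether the cell cycle genes rose in the same cells as the neutrophil and erythroid genes was not tested. Genes of the heat shock and unfolded protein response were lower, with 16 of 18 negative, 0 past the threshold and 3 adjusted over the list alone, among them the endoplasmic reticulum chaperone Hspa5 at -0.27 ± 0.07. By camera, endothelial, mural, fibroblast, reactive astrocyte and ependymal lists were higher, kept in 4, 5, 3, 4 and 5 of 6 fits with a library left out. Pan-neuronal, inhibitory and excitatory dorsal horn neuron genes were lower, kept in 4, 5 and 5 of those fits. All 18 lists called in spinal cord were lost with an estimated correlation (adjusted p = 0.685 with an estimated correlation for the neutrophil, cell cycle and heat shock lists). Without day-6 library 2, 818 genes were called; without any other single library, and with the meningeal covariate chosen after seeing the data, the count stayed at 0.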

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

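The tests of explanations in this part were chosen after the results were seen, while the difference between tissues and the splits of the samples had been planned. At day 6 the response differed between paw and DRG for 82 genes, by a test of the interaction. For 9 of the 10 genes with the smallest p the differences, paw minus DRG on the log2 scale, were 1.76 for Rassf4, 1.06 for Cd74, 1.36 for Arhgap30, 1.21 for H2-DMb1, 2.17 for Pld4, 1.33 for Lcp1, 1.90 for Mgl2, 2.11 for Mpeg1 and 0.89 for H2-Eb1. Of 100 splits of the samples within the tissues, 7 gave a count as large, the real split included, with 197 as the highest other, so chance was not excluded by the count. The 9 splits that kept the paw groups as labelled called 78 to 197 genes and the other 91 called at most 3, which points to the paw groups as the structure behind the count. At day 1 all 100 splits gave at least the real count of 0, with 29 as the highest other.

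The first pattern weighed was the 102 genes higher in paw on day 6, among them monocyte, macrophage and MHC class II genes, with a median log2 fold change of 1.46. The biopsy of control 1, with little muscle, was argued against as the whole cause. The 29 tested members of the macrophage and MHC class II lists had a median of 1.31 with it and 1.498 without it, and 39 of the 102 genes passed in a fit without it. The members were fixed before the data, but these lists were chosen after their calls with control 1 were seen, which favours lists that keep their rise. Day 6 against day 1 does not contrast control 1. There camera with its preset correlation kept both lists higher whichever library was left out (adjusted p at most 3.76e-11 for each), though the macrophage call was lost with an estimated correlation. Muscle content in general was argued against as well, since those members had a median of 1.31 with the muscle score as a covariate. A lower share of keratinocytes would raise the other cell types alike, and the medians of 7 other cell-type lists had a median of 0.0379, against 1.34 for the macrophage and monocyte markers, though basal keratinocyte genes were lower with a median of -0.41. Entry of myeloid cells after the agonist, a change of expression in resident cells, and an effect of the time or number of injections may each account for it and stay open.

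The second pattern was the 25 genes higher in DRG on day 1, with a median log2 fold change of 0.86, which hold NF-κB, adhesion and chemokine genes. Control 1 had the high share of reads in no annotated feature, and 10 of the 25 genes were called again when all genes were tested without it. The other 15 lost their calls with fewer libraries and a larger SE. Their median was 0.618 ± 0.098 with control 1 and 0.608 ± 0.114 without it (median SE), above the bound of 0.309. The size of the change in these genes thus did not rest on control 1. But the 25 genes were picked with control 1 among the samples, and passing favoured genes whose controls agreed. Little change was therefore likely from the start, so this test gives no verdict on control 1 as the cause. For list members, most of them without a call, the rule could not decide. The 40 tested members of the LTβR, lymphoid-organising and chemokine lists had a median of 0.378 with control 1 and 0.379 without it. The median SE was 0.21 without it, against a bound of 0.19, but that is the spread of single members. As a set, 36 of the 40 were positive without it. Camera with its preset correlation kept all 3 lists whichever library was left out (adjusted p at most 2.08e-08, 5.38e-06 and 5.38e-06). The median of these members thus hardly moved without control 1. But the 3 lists were chosen after their calls with control 1 were seen, and the calls were lost with an estimated correlation. Camera with its preset correlation also called between 6 and 25 lists in the other splits of these samples. The kept calls therefore give no verdict on control 1 as the whole cause for the lists. Muscle carried along with the ganglia was argued against as the whole cause, since those members had a median of 0.410 with the muscle score as a covariate, above the bound of 0.19 by more than the median SE of 0.18. More endothelial cells stay open for list members: the endothelial markers had a median of 0.0676 with an interquartile range of 0.313. This lay under the bound of 0.429, taken from the 25 picked genes, by more than that range. It lay under the bound of 0.19, taken from list members, by less than that range. More connective, mural or meningeal tissue stays open: its 44 list members had a median of 0.180, under the bound of 0.429 but by less than their interquartile range of 0.308. More macrophages in the ganglia stay open too, since 36 members of the macrophage and microglia lists had a median of 0.221 with an interquartile range of 0.456. An effect of the agonist that reached the ganglia may account for the pattern, as a hypothesis; direct action on DRG cells and signals from the paw were not tested apart.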

How the results depend on the processing

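Of the alternatives tried here, the muscle and meningeal covariates and the block across tissues were tests chosen only after the results were seen. In the order paw day 1, paw day 6, paw day 6 against day 1, DRG day 1, DRG day 6, DRG day 6 against day 1 and spinal cord, DESeq2 called 209, 509, 737, 131, 2, 106 and 64 genes, and 59 and 234 for the tissue difference at day 1 and day 6. In the simulated data DESeq2 made more false calls than edgeR; otherwise the cause was not tested. limma voom called 623 genes for paw day 6 against day 1. With only the groups compared in the fit, and so fewer samples, 0 genes were called in paw on day 1, 0 in paw on day 6 and 11 in DRG on day 1. Without the filter, 27 genes were called for DRG day 6 against day 1. With the replicate block, 0 genes were called in paw on day 1, 0 were shared by both days in paw and 7 lists were called in DRG on day 6. The numbers were not used to pair the samples: libraries of the same number had residual correlations of -0.642 to 0.317 within paw, -0.692 to 0.241 within DRG and -0.600 to -0.180 within spinal cord. Between paw and DRG of the same group and number they were -0.0578 to 0.531, with 6 of 9 over 0.1 and a mean of 0.211, against -0.0952 for different numbers, and not every library correlated best with its own number. A replicate block of these pairs across tissues gave 0 genes for the tissue difference at day 1 and 34 at day 6, 31 of them shared with the 82. With the muscle covariate, paw gave 2, 211 and 367 genes and 13 lists on day 1, and DRG gave 8 lists on day 6; with the meningeal covariate spinal cord gave 11 lists. For these the cause was not tested.

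With an estimated correlation camera called 0, 2, 1, 0, 0, 0 and 0 lists in the same order, and fry 1, 6, 5, 5, 0, 5 and 0, and fry asks a different question of a list. Leaving out each library in turn gave 0 to 1, 0 to 155, 0 to 141, 8 to 35, 0, 1 to 24 and 0 to 818 genes, and 13 to 21, 17 to 25, 10 to 18, 19 to 23, 4 to 9, 16 to 22 and 14 to 24 lists. The shared calls were 0 throughout, and the tissue difference gave 0 to 1 genes at day 1 and 19 to 173 at day 6. The highest count in spinal cord was without day-6 library 2, and leaving out libraries leaves 2 in a group.

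Leaving out libraries turned the direction of genes that did not pass, in 6 of 1260 recalculations; in another 353 a gene lost its call and in 23 it gained one. With the other settings 0 of 1717 turned, 76 lost and 76 gained a call. The log2 fold change of Icam1 in paw on day 6 ran from -0.29 to 0.38, that of Ltbr in paw on day 6 from -0.22 to 0.021, that of Nfkb2 in DRG on day 6 from -0.0060 to 0.27, and that of Ltbr in DRG between the days from -0.10 to 0.0038.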

Other observations

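The test of the clock genes was chosen after the values were seen, and the splits of the samples had been planned. In DRG on day 1, Arntl had a log2 fold change of 1.07 ± 0.12 and Npas2, its relative, of 0.73 ± 0.14, while the genes of opposite phase Dbp and Per3 were at -0.66 ± 0.17 and -0.56 ± 0.16. Of these only Arntl passed over all genes, and Npas2, Dbp and Per3 were chosen after their values were seen. An index of the genes of both phases was 0.56 on day 1 and -0.59 in controls, a difference of 1.15 ± 0.22 (SE, n = 3 per group, 2-sided exact permutation p = 0.1, the smallest possible), and differed from controls by 0.62 ± 0.23 on day 6. For a time of collection shared by paw and DRG, the paw index differed by -0.81 ± 0.55 (exact permutation p = 0.3). Adding 2 SE gave 0.28, or 0.50 without paw control 1, under the bound of 0.57 set from DRG. With 3 libraries per group 2 SE is a narrow margin, and the paw controls alone ran from -0.50 to 1.36. The test therefore cannot exclude a shared time. Clock genes also moved in paw. The fixed circadian clock list was higher in paw on day 1 than in controls (camera adjusted p = 0.0170), kept in 3 of 6 fits with a library left out. It was lower on day 6 than on day 1, kept in all 6 (camera adjusted p at most 0.0260). Both calls were lost with an estimated correlation. In paw, Per2 was at 12.0, 24.0 and 70.5 CPM in controls, 76.9, 48.4 and 61.9 on day 1 and 16.5, 23.7 and 29.2 on day 6. Control 1 of DRG was argued against as the cause of the DRG pattern, since the difference of the DRG index was 1.33 ± 0.12 without it. Collection times are not given in the sources used here, so a difference in time, shared or for DRG alone, may still account for it, as may an effect of the agonist.

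For the splits within a tissue, 10 are too few for a share under 0.05, so the values are given without a verdict. For genes, the real count and the highest other were 1 and 0 in paw on day 1, 108 and 0 on day 6, and 157 and 0 between the days, with 1 split each reaching the real count. They were 26 and 152 in DRG on day 1 (2 splits), 0 and 0 on day 6 (10 splits), and 16 and 1 between the days (1 split). For lists, they were 21 and 21, 17 and 22, and 13 and 21 in paw (2, 5 and 5 splits), 24 and 25, 4 and 14, and 20 and 18 in DRG (2, 9 and 1 splits), and 18 and 23 in spinal cord (3 splits). The DRG split with 152 genes set day-1 library 1, control 2 and control 3, which had the most muscle RNA, against the rest, which points to muscle content as a structure of those samples.

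In spinal cord the real split gave 0 genes, so all 10 splits gave at least as many, and the highest other gave 1320. That split set day-6 libraries 1 and 3 and day-1 library 2 against the rest, the libraries with high and low meningeal scores, which points to a structure of the samples other than their groups. Day-6 library 1 also had the highest neutrophil score, 2.52, with the other libraries between -1.56 and 0.82.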
